A study of Rattus norvegicus with 12 samples.

How the data were processed

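RNA was measured in micropunches of the rostral ventrolateral medulla (RVLM) of male F344 rats, an inbred strain, aged 3 months (young), 12 months (middle-aged) or 24 months (aged), with 3 animals per group. Per the labels, the rats were decapitated under isoflurane, the brains were frozen, and total RNA was labelled with 1 dye and hybridised to whole rat genome arrays. There were 12 arrays for 9 animals, because replicate 3 of each group was hybridised to a pair of arrays. The arrays sat on 3 slides. Slide 1 held young replicates 1 and 2, 1 array of young replicate 3, and middle-aged replicate 1. Slide 2 held middle-aged replicate 2, 1 array of middle-aged replicate 3, and aged replicates 1 and 2. Slide 3 held the other array of young replicate 3, the other array of middle-aged replicate 3, and both arrays of aged replicate 3. Slide is therefore partly confounded with age, and slide 3 alone held all 3 ages.

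The deposited array files hold fluorescence intensity on a linear scale, made by the authors with Agilent Feature Extraction 9.5.1.1. The signal used here was the processed signal, which per the file headers was background-subtracted with spatial and multiplicative detrending; no scaling between arrays had been applied. Flags per spot, which are 0 or 1 in the deposited files, gave saturation, outlier spots and spots well above background. The deposited series matrix holds a score: its values have mean 0 and SD 1 within each array over 36424 features, 271 of them control features, and correlate at 1.0 with the log2 processed signal. The base of its logarithm and the rule that chose its features are not known, and it served as an alternative only.

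Each array had 43379 non-control spots, of which 57 to 140 were set missing as outliers and 0 were saturated. The share of spots well above background was 73.5% to 77.1%, and the median processed signal was 97.3 to 130.2. The number of arrays limits the precision. Signals were taken as log2, spots of the same probe were averaged, and each array's 75th percentile over non-control probes was subtracted. Both arrays of replicate 3 were then averaged, so that the unit was the animal. Of 41012 probes, 29797 were well above background on every array of at least 1 group and were kept. Gene names came from the current RefSeq annotation by accession (10735 and 67 probes by their systematic and listed accessions) or by name or synonym (9274 probes). For 3390 probes the name in the file was kept, and 17546 probes had no gene name. For each gene the kept probe with the highest mean signal was used, and probes without a name stayed as their own items, which gave 25444 items, 14151 of them with a gene name and 1902 of those predicted loci. Positions of probes are those in the array files, on the rat genome build rn3 per the file headers, counted from 1.

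Group means were fitted with limma 3.58.1 in R 4.3.3 over all 9 animals, with 3 contrasts and empirical Bayes moderation (prior degrees of freedom 2.58). An item passed when its limma p, two-sided and adjusted by the method of Benjamini and Hochberg over all items, was under 0.05; the words rose and fell are used for such items. A moderated F test over the contrasts asked whether any age differed. Values with ± are log2 differences with the limma standard error (SE), with n = 3 animals per group. Where no array of a group was well above background for a gene, the fold is given as a bound: the dim group's signal on each array was raised to at least the lowest signal that was well above background on that array. The same bound is given for passed genes with a group well above background on part of its arrays. The words at least before a fold refer only to this floor on the dim signal in the main fit. They set no limit for the spread between animals or for other processing. Alternatives described below gave smaller folds for some of these genes.

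Gene lists, 37 in number, of pathways and of markers of the cell types that a punch could hold were fixed before the data were examined, as were the tests and the alternatives not named as added. Of 978 genes on them, 857 were tested. Each list was tested with limma's camera, with the preset inter-gene correlation of 0.01, adjusted over the 37 lists of a comparison. Camera with an estimated correlation, and fry, which tests whether a list's genes move one way on balance without comparing them with other genes, were alternatives. Member counts are given over all items and adjusted over the list alone. Some genes stand on more than 1 list: Ctss, C1qa, C1qb and C1qc are on the microglia list as well as on the MHC class II or complement lists, Cx3cr1 and Csf1r are on the receptor and microglia lists, Ccl3 and Ccl4 are on the cytokine and disease-associated microglia lists, and Psmb8 and Cd14 are also on the reactive astrocyte list.

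Genes were named by a rule. For aged against young animals it took the 10 largest rises and the 10 largest falls among named genes that passed and whose groups did not overlap; for the other comparisons it took 5 each way. Where under 3 passed in a direction, the 3 of lowest p in that direction were added as not past the threshold. Predicted loci were passed over. For each list past its threshold the rule took up to 4 members of lowest p in the list's direction, and a short fixed set of genes was always reported where tested. Genes named outside the rule are said to have been chosen after their values were seen. Il6, Tnf, Nos1 and Pnmt were on the fixed set but not among the tested items. Some genes that the rule takes are not reported here.

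Slide was added as a block in a fit of the 12 arrays with the animal as a random effect, and differences between the animals of slide 3 were computed alone. The difference of a lone pair of animals has no error. Alternatives covered background correction (normexp, offset 50), quantile normalization, the filter on dim probes, the probe or technical array used, the variance model, array weights, a replicate block, the series matrix, the threshold (adjusted p under 0.1, or unadjusted p under 0.05 with at least 1.5-fold), and leaving out each animal. The analysis was tested on simulated data: with 50 genes changed per fold, 48% were recovered at 1.5-fold, 80% at 2-fold, and 96% at 3-fold and at 4-fold, while 12 of the unchanged items were called. A simulated slide shift of 1 log2 unit in 200 items gave a median of 0.84 between aged and young animals without the block and 0.01 with it. Files were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and figures drawn with matplotlib 3.10.9.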

Results

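The RVLM is the brainstem region whose neurons drive sympathetic nerves to the heart and blood vessels. RNA levels in it were measured by 1-colour microarray in 3 young, 3 middle-aged and 3 aged rats, to ask which genes, and immune genes in particular, differ with age. On the 12 arrays 73.5% to 77.1% of spots were well above background and 0 were saturated. The number of animals limits the precision. The 2 arrays of 1 animal differed by a median of 0.06 log2 units, and animals of the same group by 0.103 to 0.155. On the second principal component (21.7% of variance) young replicate 2, middle-aged replicate 3 and aged replicate 3 lay apart, at 23.31, 15.6 and 28.0 against −17.78 to 2.89. Of 25444 items tested, 284 differed among the 3 ages by the moderated F test, 192 of them with a gene name. This count was 174 with slide as a block, and 130, 71, 149, 155 and 178 without young replicate 2, young replicate 3, aged replicate 1, aged replicate 2 and aged replicate 3.

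The comparison of aged with young animals asked what differs across the widest age gap. Genes of microglia, the resident macrophages of the brain, were higher in the aged RVLM, and genes of cholesterol synthesis were lower. Trem2, a lipid-sensing receptor of microglia, was 3.5-fold higher (1.81 ± 0.11, n = 3 per group, adjusted p = 0.00042), and C3, the central protein of the complement cascade, was 3.28-fold higher (1.71 ± 0.10, adjusted p = 0.00039). Cyp51, an enzyme of the later steps of cholesterol synthesis, fell by 0.99 ± 0.08 (adjusted p = 0.001). Of 25444 items 376 rose and 131 fell, of which 257 and 88 had a gene name. At an unadjusted p under 0.05 there were 2331 and 1491. The 223 rises and 81 falls of genes with a name other than a predicted locus each had 3 aged animals outside the range of the 3 young, which chance gives 10% of genes not chosen by a test; these were, so it is no separate evidence. With slide as a block 304 items passed (246 higher and 58 lower), 270 of them among the 507, and 481 of the 507 had an unadjusted p under 0.05. Without young replicate 2, young replicate 3, aged replicate 1 or aged replicate 2 the count was 302, 246, 307 or 287.

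Microglial genes rose together in the aged animals. Of 30 tested members of the microglia list 17 rose, 0 fell and 13 did not pass, and 27 rose adjusted over the list alone. The median difference was 0.75 (camera adjusted p = 9.68e-30; adjusted p = 0.037 with an estimated correlation), 0.77 with slide as a block and 0.77 on slide 3. Relative to the young mean, the median of the list was −0.09 to 0.11 in the young animals, 0.35 to 0.50 in the middle-aged and 0.67 to 0.85 in the aged. Besides Trem2, its signalling adaptor Tyrobp rose by 1.37 ± 0.11 (adjusted p = 0.00095), the integrin chain Itgb2 by 1.24 ± 0.09 (adjusted p = 0.00066) and the inhibitory Fc receptor Fcgr2b by 1.76 ± 0.15 (adjusted p = 0.0014). Aif1, the gene of the microglial stain Iba1, rose by 0.91 ± 0.10 (adjusted p = 0.0036). Blocked by slide, these differences were 1.73 for Trem2, 1.31 for Tyrobp, 1.23 for Itgb2, 1.76 for Fcgr2b and 0.84 for Aif1, and all 5 passed; on slide 3 they were 1.60, 1.39, 1.21, 1.61 and 0.77.

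Genes that microglia raise in disease and ageing were higher as well: 4 of 25 tested members rose, 0 fell and 21 did not pass, and 14 rose and 1 fell adjusted over the list alone. The median was 0.31 (camera adjusted p = 1.43e-06; adjusted p = 0.0223 with an estimated correlation), 0.30 with slide as a block and 0.49 on slide 3. The chemokines Ccl3 and Ccl4, which draw leukocytes, rose 4.59-fold (2.20 ± 0.23, adjusted p = 0.0032) and at least 3.41-fold (difference 2.37 ± 0.40, adjusted p = 0.024). Ccl4 is given as a bound since 1 of 4 young arrays was well above background for it. Lgals3, a galectin of phagocytes, rose by 1.80 ± 0.22 (adjusted p = 0.0048) and the lysosomal protease Ctsz by 0.89 ± 0.12 (adjusted p = 0.0075). In the fit with slide as a block Ccl3, Ccl4, Lgals3 and Ctsz differed by 2.13, 2.73, 1.72 and 0.90, and on slide 3 by 2.81, 2.14, 1.56 and 0.81. Ccl4 lost its call without young replicate 3 or any 1 of the aged animals (highest adjusted p = 0.0815, without aged replicate 2).

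**Figure D1:**
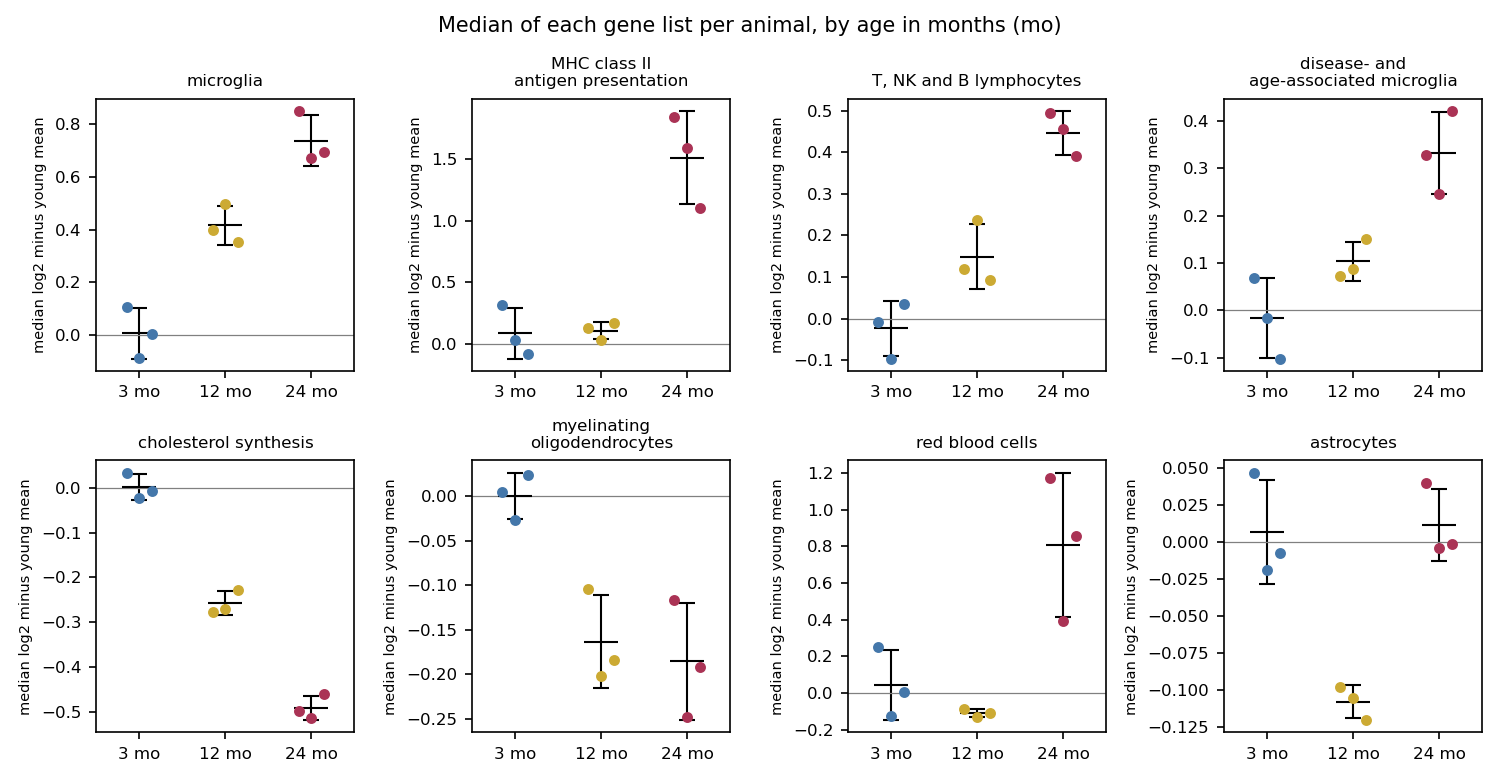
Median log2 signal of 8 gene lists in each animal, minus the mean of the young animals, against age in months; points are animals, horizontal lines are group means and error bars are SD (n = 3). The microglial median lies at 0.67 to 0.85 in the aged animals and 0.35 to 0.50 in the middle-aged, while the cholesterol synthesis median lies at −0.51 to −0.46 and −0.28 to −0.23.

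MHC class II genes, by which cells present antigen to helper T cells, were higher in the aged animals by a median of 1.67; 4 of 11 rose, 0 fell and 7 did not pass, and 10 rose adjusted over the list alone. Camera gave an adjusted p of 1.43e-09, and adjusted p = 0.121 with an estimated correlation. The median was 0.95 with slide as a block and 0.97 on slide 3. The lysosomal protease Ctss rose by 0.98 ± 0.10 (adjusted p = 0.0032), the thiol reductase Ifi30 by 0.56 ± 0.09 (adjusted p = 0.019) and the class II chain RT1-Ba by 1.67 ± 0.33 (adjusted p = 0.042). Cd86, a costimulatory molecule, was at least 1.88-fold higher in the aged, and its difference of 1.74 ± 0.20 (adjusted p = 0.0045) became 0.43 ± 0.58 (adjusted p = 0.82) with slide as a block. As 0 young arrays were well above background for it, neither size is exact, and the bound does not hold with the block. The call of Cd86 was also lost without a slide term on 12 arrays with the animal as a random block (adjusted p = 0.332), and with normexp background correction (0.15, adjusted p = 0.81). RT1-Ba was 1.5 ± 0.40 (adjusted p = 0.15) with the block, a smaller difference with a larger SE, and 0.74 (adjusted p = 0.0657) with normexp. Quantile normalization, the series matrix values, no filter on dim probes and a fit of only the groups compared ended its call too. On slide 3 Ctss, Ifi30, RT1-Ba and Cd86 differed by 0.97, 0.61, 1.53 and 0.92. The class II chaperone Cd74 (2.05 ± 0.43, adjusted p = 0.055) and the class II chain RT1-Da (2.07 ± 0.49, adjusted p = 0.083) did not pass, with Cd74 levels spread over the young animals from −1.65 to 0.02. RT1 genes have close paralogs, so a probe may read more than 1 of them. RT1-Ba lost its call without 8 of the 9 animals (highest adjusted p = 0.114, without young replicate 3), and Ifi30 without young replicate 2 or 3 or aged replicate 1 or 3 (highest adjusted p = 0.0794, without young replicate 2).

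MHC class I genes and the proteasome that feeds them were higher by a median of 0.25, with 4 of 21 risen, 0 fallen and 17 not past, and 9 risen adjusted over the list alone (camera adjusted p = 1.41e-06). The list had adjusted p = 0.19 with an estimated correlation. The median was 0.27 with slide as a block and 0.21 on slide 3. The immunoproteasome subunits Psmb8 and Psmb9 rose by 0.71 ± 0.11 (adjusted p = 0.018) and 0.75 ± 0.13 (adjusted p = 0.025). The class I light chain B2m rose by 0.52 ± 0.10 (adjusted p = 0.031) and the peptide transporter Tap2 by 0.75 ± 0.15 (adjusted p = 0.044). Blocked by slide, Psmb8 and Psmb9 differed by 0.71 and 0.81 and passed, and B2m and Tap2 differed by 0.45 ± 0.10 (adjusted p = 0.08) and 0.64 ± 0.15 (adjusted p = 0.088), smaller differences with a like SE. On slide 3 Psmb8, Psmb9, B2m and Tap2 differed by 0.65, 0.66, 0.49 and 0.61. Psmb8 lost its call without young replicate 2 or 3 (highest adjusted p = 0.0737), Psmb9 without 4 of the 9 animals (0.0982), and B2m and Tap2 without 7 each (0.118 and 0.136).

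Complement genes were higher in the aged animals: 7 of 22 rose, 0 fell and 15 did not pass, and 9 rose and 1 fell adjusted over the list alone. The median was 0.36 (camera adjusted p = 7.44e-05; adjusted p = 0.2 with an estimated correlation), 0.31 with slide as a block and 0.42 on slide 3. After C3, the C1q chains C1qb and C1qc, which start the classical pathway, rose by 0.74 ± 0.10 (adjusted p = 0.0077) and 0.56 ± 0.09 (adjusted p = 0.017). C4a rose by 1.18 ± 0.19 (adjusted p = 0.02). With slide as a block C3, C1qb and C4a differed by 1.62, 0.70 and 1.17 and passed; C1qc at 0.52 ± 0.11 (adjusted p = 0.067) did not, from a smaller difference with a larger SE. On slide 3 C3, C1qb, C1qc and C4a differed by 1.60, 0.84, 0.66 and 1.25. C1qc lost its call without young replicate 2 or 3 or any 1 of the aged animals (highest adjusted p = 0.071), and C4a without young replicate 2 or 3 or aged replicate 1 or 2 (0.0785).

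Cytokines and chemokines were higher by a median of 0.26, with 3 of 27 risen, 0 fallen and 24 not past, and 9 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.000431). Camera gave adjusted p = 0.19 with an estimated correlation. The members that rose were Ccl3, Ccl4 and the T cell attractant Ccl5 (1.39 ± 0.16, adjusted p = 0.0042; 1.15 with slide as a block and 0.97 on slide 3). Ccl5 lost its call on 12 arrays with the animal as a random block (adjusted p = 0.0782). Il1b differed by 0.69 ± 0.40 (adjusted p = 0.46) and Il18 by 0.38 ± 0.09 (adjusted p = 0.072), and neither passed. Of 29 cytokine and chemokine receptors 3 rose, 0 fell and 26 did not pass, and 11 rose adjusted over the list alone, with a median of 0.10 (camera adjusted p = 0.0019). These genes had adjusted p = 0.203 with an estimated correlation. Il6r rose by 0.52 ± 0.08 (adjusted p = 0.011), the fractalkine receptor Cx3cr1 by 0.67 ± 0.12 (adjusted p = 0.031) and the TNF receptor Tnfrsf1b by 0.77 ± 0.15 (adjusted p = 0.043). Blocked by slide, Il6r was 0.55 and passed, while Cx3cr1 was 0.58 ± 0.12 (adjusted p = 0.051), a smaller difference, and Tnfrsf1b 0.75 ± 0.19 (adjusted p = 0.13), with a larger SE. With normexp Tnfrsf1b was 0.42 (adjusted p = 0.0519) and Il6r 0.37 (adjusted p = 0.0537), and 13 of 23 settings ended the call of Tnfrsf1b. The receptor list lost its call without aged replicate 1 (median 0.07, adjusted p = 0.0552), as did Il6r without that animal or young replicate 3 (highest adjusted p = 0.0511). Without aged replicate 3 the receptor median was 0.21. Cx3cr1 and Tnfrsf1b lost theirs without 6 and 7 of the 9 animals (highest adjusted p = 0.115 and 0.153). On slide 3 the medians of the cytokine and receptor lists were 0.28 and 0.12, and with the block 0.25 and 0.11.

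Toll-like receptor, NF-kappaB and inflammasome genes were higher by a median of 0.18, with 3 of 26 risen, 0 fallen and 23 not past, and 11 risen and 1 fallen adjusted over the list alone (camera adjusted p = 0.000339). This became adjusted p = 0.176 with an estimated correlation, and the median was 0.20 with slide as a block and 0.23 on slide 3. The inflammasome adaptor Pycard rose by 0.93 ± 0.14 (adjusted p = 0.014), the endotoxin co-receptor Cd14 by 0.62 ± 0.11 (adjusted p = 0.029) and the sensor of double-stranded RNA Tlr3 by 0.37 ± 0.07 (adjusted p = 0.045). Pycard was 0.89 with the block and passed; Cd14 at 0.56 ± 0.15 (adjusted p = 0.15) and Tlr3 at 0.32 ± 0.08 (adjusted p = 0.1) did not, with smaller differences and larger SE. Pycard lost its call without young replicate 2 or 3 or aged replicate 2 (highest adjusted p = 0.0626), Cd14 without 7 of the 9 animals (0.11) and Tlr3 without 8 (0.155). Of 42 interferon-stimulated genes only Lgals3bp rose (0.64 ± 0.12, adjusted p = 0.037; 0.66 ± 0.14 and adjusted p = 0.059 with the block, from a larger SE), 0 fell and 41 did not pass, and 1 rose adjusted over the list alone. Their median was 0.28 (camera adjusted p = 3.99e-06; adjusted p = 0.19 with an estimated correlation), 0.27 with the block and 0.31 on slide 3. Lgals3bp lost its call without 8 of the 9 animals (highest adjusted p = 0.136, without young replicate 2).

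Genes of T, NK and B lymphocytes were higher by a median of 0.49, with 3 of 14 risen, 0 fallen and 11 not past, and 8 risen adjusted over the list alone. Camera gave an adjusted p of 3.24e-06, and adjusted p = 0.0225 with an estimated correlation; the median was 0.72 with slide as a block and 0.77 on slide 3. Cd6, a receptor of T cells, rose by 1.24 ± 0.14 (adjusted p = 0.0043; 1.16 with the block). Cd4, which rat macrophages and microglia also carry, was at least 3.06-fold higher (adjusted p = 0.0048; difference 1.92 with the block), and Prf1, the pore-forming protein of cytotoxic lymphocytes, at least 2.21-fold higher (adjusted p = 0.022). Prf1 went from 2.25 ± 0.38 to 1.79 ± 0.51 (adjusted p = 0.18) with the block, sizes that are not exact with 0 young arrays well above background, and lost its call without young replicate 3 or aged replicate 1 or 3 (highest adjusted p = 0.0814). Normexp background correction ended the calls of Cd4 and Prf1. Of 13 genes of perivascular macrophages, monocytes and neutrophils 2 rose, 0 fell and 11 did not pass, and 7 rose and 2 fell adjusted over the list alone. The median was 0.31 (camera adjusted p = 0.00547; adjusted p = 0.339 with an estimated correlation), 0.50 with the block, 0.77 on slide 3 and 0.49 without young replicate 1. The hyaluronan receptor Lyve1 rose by 0.80 ± 0.10 (adjusted p = 0.0048; 0.95 with the block) and the chemokine Pf4 by 0.95 ± 0.19 (adjusted p = 0.045). Pf4 was 0.90 ± 0.21 (adjusted p = 0.095) with the block, from a smaller difference and a larger SE, and lost its call without 8 of the 9 animals (highest adjusted p = 0.149). The neutrophil gene S100a9 differed by 1.99 ± 0.42 and did not pass (adjusted p = 0.055).

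Red blood cell genes moved with these immune genes in the aged animals. Of 7 tested members 0 passed over all items and 6 rose adjusted over the list alone, and the median was 0.86 (camera adjusted p = 8.4e-06; adjusted p = 0.176 with an estimated correlation), 0.81 with slide as a block and 0.87 on slide 3. Per animal the median relative to the young mean was −0.13 to 0.25 in the young, −0.13 to −0.09 in the middle-aged and 0.39 to 1.17 in the aged. The globin gene Hbb-b1 differed by 0.72 ± 0.16 (adjusted p = 0.07) and did not pass.

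Cholesterol synthesis genes fell together in the aged animals: 15 of 23 fell, 0 rose and 8 did not pass, and 21 fell and 1 rose adjusted over the list alone. The median was −0.50 (camera adjusted p = 1.83e-24; adjusted p = 0.00722 with an estimated correlation), −0.51 with slide as a block and −0.42 on slide 3. The isomerase Idi1 fell by 0.66 ± 0.08 (adjusted p = 0.006) and the sterol reductase Tm7sf2 by 0.70 ± 0.07 (adjusted p = 0.0033). With the block Cyp51, Idi1 and Tm7sf2 differed by −1.05, −0.66 and −0.75 and all 3 passed, and on slide 3 they differed by −0.91, −0.65 and −0.60.

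Genes of myelinating oligodendrocytes were lower by a median of −0.23, with 3 of 25 fallen, 1 risen and 21 not past, and 10 fallen and 4 risen adjusted over the list alone (camera adjusted p = 0.000276). The same list had adjusted p = 0.159 with an estimated correlation, and the median was −0.26 with slide as a block, −0.32 on slide 3 and −0.12 without aged replicate 2. Ugt8, which makes the myelin lipid galactosylceramide, fell by 0.95 ± 0.12 (adjusted p = 0.0054), and Mal, a membrane protein of myelin, by 0.52 ± 0.07 (adjusted p = 0.0078). Mal was −0.55 with the block and passed; Ugt8 was −1.34 ± 0.29 (adjusted p = 0.072), a larger difference with a larger SE. The call of Ugt8 was also lost without a slide term on 12 arrays with the animal as a random block (−0.95, adjusted p = 0.246), and with only technical replicate 2 (−0.92, adjusted p = 0.0612). Ninj2, chosen after its values were seen, rose by 0.31 ± 0.06 (adjusted p = 0.041). With the block it was 0.29 ± 0.07 (adjusted p = 0.098), from a larger SE, and its call was lost without any 1 of the 9 animals (highest adjusted p = 0.138). Mbp differed by −0.60 ± 0.18 and did not pass (adjusted p = 0.18). Of 17 genes of oligodendrocyte precursors 0 passed over all items or adjusted over the list alone, and the median was −0.10 (camera adjusted p = 0.0176). The precursor list had adjusted p = 0.176 with an estimated correlation and a median of −0.06 with the block and −0.08 on slide 3. It lost its call without young replicate 1 or aged replicate 2 (medians −0.01 and −0.04, highest adjusted p = 0.0729).

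Extracellular matrix genes were lower by a median of −0.32, with 3 of 37 fallen, 0 risen and 34 not past, and 6 fallen adjusted over the list alone (camera adjusted p = 1.41e-06). The list had adjusted p = 0.2 with an estimated correlation, and the median was −0.28 with slide as a block and −0.28 on slide 3. It was −0.16 without young replicate 1 (adjusted p = 0.00103) and −0.20 without aged replicate 3. The basement membrane proteins Nid1 and Nid2 fell by 0.74 ± 0.13 (adjusted p = 0.03) and 0.55 ± 0.09 (adjusted p = 0.025), and the collagen chaperone Serpinh1 by 0.51 ± 0.08 (adjusted p = 0.018). Nid1 and Serpinh1 were −0.80 and −0.59 with the block and passed; Nid2 was −0.51 ± 0.11 (adjusted p = 0.087), with a larger SE. Nid1 and Serpinh1 lost their calls without 5 of the 9 animals each (highest adjusted p = 0.1 and 0.0704, without aged replicate 2), and Nid2 without young replicate 3 or any 1 of the aged animals (0.0884). Markers of meninges and fibroblasts, which share the collagens Col1a1 and Col1a2 with the matrix list, moved the same way. The median of 15 was −0.38, 0 passed over all items, and 3 fell adjusted over the list alone (camera adjusted p = 7.44e-05). Camera gave adjusted p = 0.393 with an estimated correlation, and the median was −0.44 with the block and −0.35 on slide 3. Their medians in young replicates 1, 2 and 3 were 0.82, −0.47 and −0.36 relative to the young mean, and without young replicate 1 the difference was 0.01 (adjusted p = 0.133), and without young replicate 2 it was −0.63. Lum and Igf2, genes of meningeal fibroblasts, differed by −0.48 ± 0.10 (adjusted p = 0.05, just above the threshold) and −1.04 ± 0.28 (adjusted p = 0.13).

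C1, pan-neuronal, RVLM receptor, glutamate, and GABA and glycine lists had medians between −0.17 and 0.00 in aged against young animals. Of 17 genes of C1 neurons, the catecholaminergic cells of the RVLM, 0 passed over all items and 1 fell adjusted over the list alone, and the median was −0.17 (camera adjusted p = 0.0497). These genes had adjusted p = 0.2 with an estimated correlation, and the median was −0.14 and camera adjusted p = 0.0598 with slide as a block, −0.17 on slide 3. Dbh, which makes noradrenaline, differed by −0.93 ± 0.20 (adjusted p = 0.063) and Th, the first enzyme of catecholamine synthesis, by −0.06 ± 0.26 (adjusted p = 0.94). Of 35 pan-neuronal genes 0 passed in either count (median −0.04, camera adjusted p = 0.0414; adjusted p = 0.47 with an estimated correlation; median −0.08 with the block and 0.14 on slide 3). The pan-neuronal list lost its call without young replicate 2 or aged replicate 1 (medians −0.02 and −0.002, adjusted p = 0.266 and 0.331), and the C1 list without young replicate 3, middle-aged replicate 1 or aged replicate 2 (highest adjusted p = 0.146; median −0.11 without the last). In all 9 of 23 settings ended the call of the C1 list, among them quantile normalization, the series matrix, the replicate block and only technical replicate 1. Of 23 settings 4 ended that of the pan-neuronal list, normexp among them. Without young replicate 1, young replicate 3 or aged replicate 3 the pan-neuronal median was −0.09, −0.10 or −0.10, and with the series matrix values it was 0.003. Of 41 genes of the angiotensin system and of neuromodulator receptors in the RVLM 2 rose, 0 fell and 39 did not pass, and 2 rose and 1 fell adjusted over the list alone (median −0.07, camera adjusted p = 0.0459; adjusted p = 0.176 with an estimated correlation; median −0.08 with the block and −0.05 on slide 3). The angiotensin receptor Agtr1a differed by −0.06 ± 0.09 (adjusted p = 0.81). This list lost its call without young replicate 1 or aged replicate 2 (highest adjusted p = 0.148), and its median was −0.11 without young replicate 1 and −0.12 without aged replicate 1. Of 23 settings 6 ended its call, among them normexp and quantile normalization.

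Glutamate transmission genes had a median of −0.07 (31 tested, adjusted p = 0.0556) and GABA and glycine transmission genes one of 0.00 (28 tested, adjusted p = 0.245). Of their members 0 passed over all items, neither list passed, and 1 GABA and glycine gene fell adjusted over the list alone. Astrocyte genes had a median of 0.03, with 0 of 20 past in either count (adjusted p = 0.656, direction down). Reactive astrocyte genes were higher by a median of 0.24, with 2 of 29 risen (Psmb8 and Cd14), 0 fallen, and 5 risen adjusted over the list alone (camera adjusted p = 0.0459). This became adjusted p = 0.416 with an estimated correlation, and the median was 0.24 with slide as a block and 0.09 on slide 3. This list lost its call without 6 of the 9 animals (highest adjusted p = 0.259, without aged replicate 1) and with the mean of a gene's probes. The median was 0.40 without young replicate 1 and 0.08 without aged replicate 2. The intermediate filament gene Gfap differed by 0.90 ± 0.23 and did not pass (adjusted p = 0.11).

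The genes with the largest rises and falls were mostly outside the lists. Gipr, the receptor of the incretin hormone GIP (probe on chromosome 1 from 78593703 to 78593762), rose 5.5-fold (2.46 ± 0.14, adjusted p = 0.00028). Pou3f1, a POU-domain transcription factor of Schwann cells and neurons (chromosome 5, 143994228 to 143994287), rose 4.19-fold (2.07 ± 0.10, adjusted p = 0.00028). Igf2bp2, an RNA-binding protein (chromosome 11, 81273629 to 81273688), fell by 1.90 ± 0.10 (adjusted p = 0.00028), and Casr, the calcium-sensing receptor (chromosome 11, 66142002 to 66142060), by 1.60 ± 0.13 (adjusted p = 0.00095). Blocked by slide, Gipr, Pou3f1, Igf2bp2 and Casr differed by 2.41, 1.90, −1.93 and −1.61 and passed, and on slide 3 they differed by 2.20, 1.90, −1.99 and −2.02. The Fc receptor-like gene Fcrl2, Bpifb4, Trim55 and Pira2 rose by 1.96 to 2.62, with adjusted p from 0.00042 to 0.0034, and Mlph, a melanosome transport protein, was at least 3.75-fold higher (adjusted p = 0.0056). Pira2, well above background on 1 of 4 young arrays, was at least 3.39-fold higher. All 5 passed with the block, at 1.55 (Pira2) to 2.55 (Bpifb4), and normexp background correction ended the calls of Mlph and Pira2, as of Alox5, Capn6 and Aoc1. Ceacam4, Cd93, the membrane metalloprotease Mmp14 and the leukotriene enzyme Alox5 fell by 1.00 to 1.53, with adjusted p from 0.0044 to 0.015, and passed with the block. Capn6 was at least 2.29-fold lower (adjusted p = 0.013; −2.40 ± 0.36 became −2.19 ± 0.55, adjusted p = 0.12, with the block, from a larger SE), and Aoc1 at least 1.32-fold lower (adjusted p = 0.045). Calls were lost for Capn6 without young replicate 1 or 2 (highest adjusted p = 0.0559), Aoc1 without 7 of the 9 animals (0.153). They were also lost for Ceacam4 without young replicate 2 or 3 (0.0626) and Cd93 without young replicate 1 or 3 (0.0617).

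**Figure D2:**
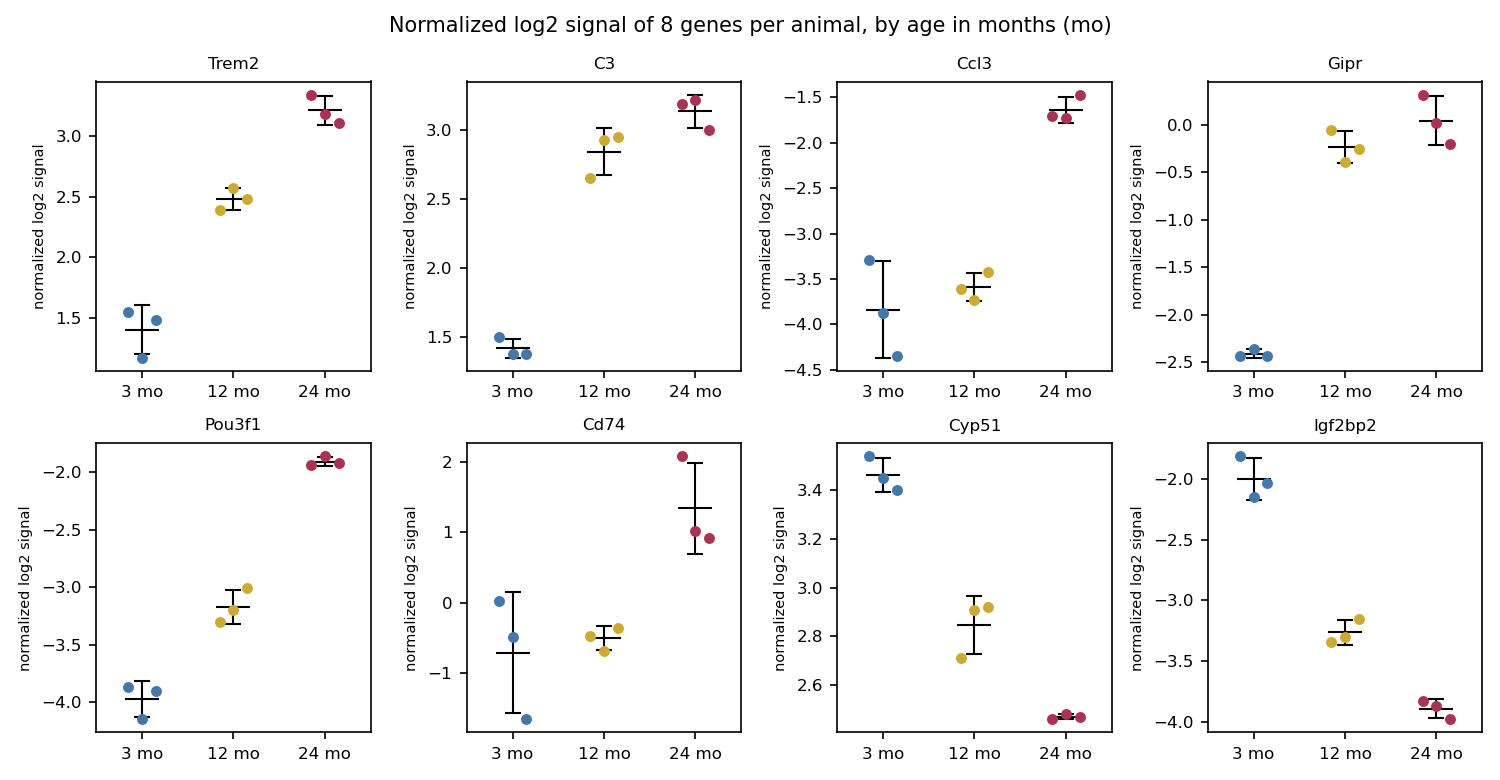
Normalized log2 signal (log2 processed signal minus the array's 75th percentile) of 8 genes in each animal against age group; points are animals, lines are means and error bars are SD (n = 3). Trem2 lies at 1.17 to 1.55 in young and 3.11 to 3.34 in aged animals, and Cd74 at −1.65 to 0.02 and 0.92 to 2.08.

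The comparison of middle-aged with young animals asked which differences were already there at 12 months. Microglial genes were higher and cholesterol synthesis and myelin genes lower in the middle-aged RVLM. Of these lists cholesterol synthesis passed with an estimated correlation (adjusted p = 0.0195), and microglia and myelin had adjusted p = 0.0735 and adjusted p = 0.0644 with an estimated correlation. Gipr was 4.54-fold higher (2.18 ± 0.14, n = 3 per group, adjusted p = 0.003), C3 2.67-fold (1.42 ± 0.10, adjusted p = 0.0047) and Trem2 2.11-fold (1.08 ± 0.11, adjusted p = 0.022), while Igf2bp2 fell by 1.27 ± 0.10 (adjusted p = 0.0081). In all, 37 items rose and 10 fell, of which 24 and 8 had a gene name. At an unadjusted p under 0.05 there were 839 and 777. The 21 rises and 8 falls of genes with a name other than a predicted locus did not overlap between groups. The test chose them, so it is no separate evidence. With slide as a block 28 items passed (23 higher and 5 lower), 26 of them among the 47. On slide 1, with 1 middle-aged and 3 young animals, 0 items passed by limma, and 1602 had an unadjusted p under 0.05. Leaving out 1 animal gave 2 items (without middle-aged replicate 1 or 2) to 23 (without young replicate 1). It gave 13, 4, 9, 13, 7 and 18 without young replicates 2 and 3, middle-aged replicate 3 and aged replicates 1 to 3. Gipr and C3 were the only named genes that passed in each of these fits and in every other setting tried, except the fit on slide 1.

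The microglia list had 4 of 30 members risen, 0 fallen and 26 not past, and 19 risen and 1 fallen adjusted over the list alone. The median was 0.39 (camera adjusted p = 3.84e-25; adjusted p = 0.0735 with an estimated correlation), 0.40 with slide as a block, 0.41 on slide 1 and 0.36 on slide 3. The risen members were Trem2, Tyrobp (0.82 ± 0.11, adjusted p = 0.037), Itgb2 (0.61 ± 0.09, adjusted p = 0.05, just below the threshold) and the prostaglandin D synthase Hpgds (1.08 ± 0.14, adjusted p = 0.034). With the block Trem2, Tyrobp and Itgb2 were 1.03, 0.78 and 0.60 and passed; Hpgds was 0.87 ± 0.17 (adjusted p = 0.2), a smaller difference with a larger SE. Without a slide term, on 12 arrays with the animal as a random block, Hpgds had adjusted p = 0.0765, and with normexp it was 0.165 (adjusted p = 0.994). It was well above background on 1 of 4 young arrays and at least 2.11-fold higher in the main fit. Trem2 lost its call without 5 of the 9 animals (highest adjusted p = 0.107, without middle-aged replicate 2), and Tyrobp, Itgb2 and Hpgds theirs without any 1 of the 9 (highest adjusted p = 0.161, 0.213 and 0.155). Red blood cell genes had a median of −0.14 and did not pass as a list (adjusted p = 0.579).

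Several other immune lists were higher by camera with the preset correlation, with few or 0 members past over all items. None of them passed with an estimated correlation. Over all lists, a mixed split of the same animals gave 19 calls by the preset correlation, against 16 for the real split. Cytokine and chemokine (median 0.07, adjusted p = 0.275), Toll-like receptor (0.075, adjusted p = 0.0778) and perivascular macrophage lists (0.08, adjusted p = 0.0953; 0.20 and adjusted p = 0.0109 with slide as a block) did not pass. Complement genes had 1 of 22 risen (C3), 0 fallen, and 5 risen adjusted over the list alone (median 0.21, camera adjusted p = 0.000196; adjusted p = 0.281 with an estimated correlation; 0.15 with slide as a block). MHC class I genes had a median of 0.18 (camera adjusted p = 1.69e-06; adjusted p = 0.281 with an estimated correlation; 0.22 with the block). Interferon-stimulated genes had a median of 0.12 (camera adjusted p = 0.000481; adjusted p = 0.335 with an estimated correlation; 0.10 with the block). Of the members of both lists 0 passed in either count. Lymphocyte genes had 2 risen adjusted over the list alone (median 0.14, camera adjusted p = 0.00151; adjusted p = 0.0925 with an estimated correlation; 0.24 with the block). Cytokine receptors had 0 (median 0.11, camera adjusted p = 0.000729; adjusted p = 0.281 with an estimated correlation; 0.12 with the block). MHC class II genes had a median of 0.10 and 2 risen adjusted over the list alone (camera adjusted p = 0.00806; adjusted p = 0.422 with an estimated correlation); with the block the median was 0.20 and camera gave adjusted p = 0.163. Disease- and age-associated microglial genes had a median of 0.12 and 1 risen adjusted over the list alone (camera adjusted p = 0.0219). The same list had adjusted p = 0.148 with an estimated correlation, and the median was 0.14 with the block. Medians on slides 1 and 3 were 0.17 and 0.22 for complement, 0.21 and 0.13 for MHC class I, and 0.21 and 0.01 for interferon-stimulated genes. They were 0.09 and 0.25 for lymphocytes, 0.11 and 0.08 for receptors, 0.14 and 0.28 for MHC class II, and 0.08 and 0.25 for disease- and age-associated microglial genes. Calls of lists were lost without young replicate 3 for MHC class II (adjusted p = 0.281), without young replicate 2 for interferon-stimulated genes (0.0561) and without 4 of the 9 animals for disease- and age-associated microglial genes (highest 0.224, without young replicate 3). Leaving out 1 animal also moved medians. Without young replicates 1, 2 and 3 and middle-aged replicate 3 in turn, that of MHC class II was 0.39, 0.19, 0.02 and 0.07. Without young replicates 2 and 3 and middle-aged replicate 3 that of lymphocytes was 0.08, 0.22 and 0.23. Without young replicates 1 and 2 and middle-aged replicates 1 and 3 that of interferon-stimulated genes was 0.18, 0.07, 0.07 and 0.19. It was 0.33 for complement without young replicate 1, and 0.07 and 0.05 for disease- and age-associated microglial genes without young replicates 2 and 3. Of 23 settings 5 ended the call of MHC class II and 9 that of disease- and age-associated microglial genes, normexp among both. With normexp background correction the MHC class II and lymphocyte medians had the opposite sign (−0.005 and −0.07), as had that of lymphocytes without the filter on dim probes (−0.02).

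Cholesterol synthesis genes were lower by a median of −0.25, with 1 of 23 fallen (Cyp51, by 0.62 ± 0.08, adjusted p = 0.034), 0 risen, and 12 fallen adjusted over the list alone (camera adjusted p = 3.93e-17). The list had adjusted p = 0.0195 with an estimated correlation. The median was −0.21 with slide as a block, −0.29 on slide 1 and −0.22 on slide 3, and Cyp51 was −0.66 with the block and passed. Myelin genes were lower by a median of −0.26, with 2 of 25 fallen, 0 risen, and 7 fallen adjusted over the list alone (camera adjusted p = 7.39e-09). Camera gave adjusted p = 0.0644 with an estimated correlation, and the median was −0.24 with the block, −0.10 on slide 1 and −0.22 on slide 3. Mal fell by 0.60 ± 0.07 (adjusted p = 0.026; −0.62 with the block) and Ugt8 by 0.82 ± 0.12 (adjusted p = 0.05, just below the threshold; −1.12 ± 0.27 and adjusted p = 0.32 with the block, from a larger SE). Ugt8 had adjusted p = 0.793 without a slide term on 12 arrays with the animal as a random block. Cyp51, Mal and Ugt8 lost their calls without any 1 of the 9 animals (highest adjusted p = 0.133, 0.126 and 0.187). Precursor genes (median −0.12, camera adjusted p = 0.00208; adjusted p = 0.104 with an estimated correlation) and astrocyte genes (median −0.07, camera adjusted p = 0.00696; adjusted p = 0.104 with an estimated correlation) were lower with 0 members past in either count. With the block their medians were −0.08 and −0.07, on slide 1 −0.14 and −0.09, and on slide 3 −0.10 and −0.15. The precursor median was −0.07 without young replicate 1, and that of astrocytes −0.10 without middle-aged replicate 1; normexp ended the astrocyte call.

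Matrix genes were lower by a median of −0.22 and meningeal genes by −0.61, with 0 members past over all items and 3 and 1 fallen adjusted over the list alone (camera adjusted p = 1.49e-06 and 8.6e-08; adjusted p = 0.281 and 0.335 with an estimated correlation). With slide as a block the medians were −0.23 and −0.56, on slide 1 −0.29 and −0.60, and on slide 3 −0.11 and −0.19. Without young replicate 1 they were −0.085 and −0.20 (adjusted p = 0.00753 and 0.00908). Among genes outside the lists, Zbtb16, a zinc-finger transcription factor, rose by 1.96 ± 0.22 (adjusted p = 0.023), Trim55 by 1.31 ± 0.13 (adjusted p = 0.015) and the protease Ctse by 1.21 ± 0.16 (adjusted p = 0.034). They passed with the block, at 1.96, 1.22 and 1.11. Casr fell by 1.45 ± 0.13 (adjusted p = 0.0084), Defa24 by 1.14 ± 0.13 (adjusted p = 0.023) and Rras2 by 0.79 ± 0.10 (adjusted p = 0.034). With the block Igf2bp2 was −1.28 and passed, while Casr at −1.43 ± 0.23 (adjusted p = 0.089), Defa24 at −1.07 ± 0.51 (adjusted p = 0.98) and Rras2 at −0.81 ± 0.13 (adjusted p = 0.074) did not, from larger SE. Defa24 had adjusted p = 0.445 without a slide term on 12 arrays with the animal as a random block. It was well above background on 2 of 4 middle-aged arrays and at least 2.11-fold lower in the main fit. With normexp Trim55 was 0.37 (adjusted p = 0.596), Casr −0.68 (adjusted p = 0.126), Defa24 −0.33 (adjusted p = 0.835) and Rras2 −0.70 (adjusted p = 0.0539), and their calls ended. Calls were lost without 6 of the 9 animals for Zbtb16 (highest adjusted p = 0.116), 4 for Trim55 (0.0943), 9 for Ctse (0.121), 3 for Casr (0.0722), 3 for Igf2bp2 (0.0709), 6 for Defa24 (0.131) and 9 for Rras2 (0.161).

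The comparison of aged with middle-aged animals asked what differs after 12 months. Pou3f1 was the only item past the threshold, 2.4-fold higher in the aged (1.26 ± 0.10, n = 3 per group, adjusted p = 0.023); at an unadjusted p under 0.05 there were 1890 items higher and 840 lower. As groups, microglial, MHC class II and red blood cell genes were higher in the aged animals and cholesterol synthesis genes lower. The first 3 had adjusted p = 0.117, 0.119 and 0.119 with an estimated correlation, and cholesterol synthesis passed with adjusted p = 0.0292. With slide as a block Pou3f1 was 1.20 (adjusted p = 0.0084, again 1 item), and on slide 3 it was 1.12. On slide 2, with a pair of animals of each age, 0 items passed by limma and 1783 had an unadjusted p under 0.05. Pou3f1 lost its call without 7 of the 9 animals (highest adjusted p = 0.125, without middle-aged replicate 2). The count was 2, 3 or 2 without young replicate 1, young replicate 2 or aged replicate 3, 1 without middle-aged replicate 2, and 0 without any other animal.

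Microglial genes were higher by a median of 0.41, with 0 of 30 past over all items and 17 risen adjusted over the list alone (camera adjusted p = 2.45e-16). These genes had adjusted p = 0.117 with an estimated correlation, and the median was 0.39 with slide as a block, 0.38 on slide 2 and 0.41 on slide 3. Trem2 differed by 0.73 ± 0.11 (adjusted p = 0.15) and Itgb2 by 0.63 ± 0.09 (adjusted p = 0.087), and neither passed. MHC class II genes were higher by a median of 0.55, with 0 of 11 past over all items and 8 risen adjusted over the list alone (camera adjusted p = 3.32e-08). This became adjusted p = 0.119 with an estimated correlation, and the median was 0.54 with the block, 0.51 on slide 2 and 0.72 on slide 3. Cd74 differed by 1.84 ± 0.43 and RT1-Da by 2.05 ± 0.49 (adjusted p = 0.26 for each), and neither passed. Disease- and age-associated microglial genes had a median of 0.21 and 4 risen adjusted over the list alone (camera adjusted p = 6.86e-06). The same list had adjusted p = 0.0292 with an estimated correlation, and the median was 0.20 with the block, 0.27 on slide 2 and 0.20 on slide 3. Lymphocyte genes had a median of 0.42 and 6 risen adjusted over the list alone (camera adjusted p = 0.00122; adjusted p = 0.101 with an estimated correlation; 0.39 with the block). Cytokine genes had a median of 0.20 and 4 risen adjusted over the list alone (camera adjusted p = 0.00135). The list had adjusted p = 0.244 with an estimated correlation, and the median was 0.21 with the block. On slides 2 and 3 the medians were 0.33 and 0.34 for lymphocyte genes and 0.15 and 0.18 for cytokine genes. Ccl5 (1.53 ± 0.16, adjusted p = 0.053) and Ccl3 (1.95 ± 0.23, adjusted p = 0.08) did not pass. Red blood cell genes moved with these lists, with a median of 0.88, 0 of 7 past over all items and 5 risen adjusted over the list alone (camera adjusted p = 3.14e-07). Camera gave adjusted p = 0.119 with an estimated correlation, and the median was 0.88 with the block, 0.82 on slide 2 and 1.03 on slide 3.

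Cholesterol synthesis genes were lower by a median of −0.24, with 0 of 23 past over all items and 14 fallen adjusted over the list alone (camera adjusted p = 2.25e-13). These genes had adjusted p = 0.0292 with an estimated correlation, and the median was −0.25 with slide as a block, −0.25 on slide 2 and −0.26 on slide 3. Myelin genes had a median of 0.07 and did not pass as a list (adjusted p = 0.534). Smaller differences, with 0 members past over all items, were found for Toll-like receptor (median 0.12, camera adjusted p = 0.00135; adjusted p = 0.186 with an estimated correlation) and complement genes (0.15, camera adjusted p = 0.0264; adjusted p = 0.58 with an estimated correlation). Interferon-stimulated genes were alike (0.14, camera adjusted p = 0.0264; adjusted p = 0.593 with an estimated correlation). MHC class I genes (0.08, camera adjusted p = 0.0376) and perivascular macrophage genes (0.27, camera adjusted p = 0.0436) each had adjusted p = 0.593 with an estimated correlation. With the block the medians of these 5 lists were 0.14, 0.15, 0.13, 0.10 and 0.24. RVLM receptor genes were lower by −0.09 (camera adjusted p = 0.00986; adjusted p = 0.117 with an estimated correlation) and pan-neuronal genes by −0.09 (camera adjusted p = 0.0127; adjusted p = 0.593 with an estimated correlation), and with the block by −0.10 and −0.08. On slides 2 and 3 the medians were 0.23 and 0.10 for Toll-like receptor, 0.14 and 0.21 for complement, 0.10 and 0.29 for interferon-stimulated and 0.19 and 0.10 for MHC class I genes. They were 0.19 and 0.18 for perivascular, −0.07 and −0.12 for RVLM receptor and −0.15 and −0.07 for pan-neuronal genes. Without middle-aged replicate 3 or aged replicate 1 the calls of MHC class I (highest adjusted p = 0.619), pan-neuronal (0.192) and complement genes (0.174, lost also without aged replicate 2) were lost. Calls were also lost for Toll-like receptor genes without aged replicate 1 (0.0667), RVLM receptors without aged replicate 2 (0.0774), interferon-stimulated genes without middle-aged replicate 3 or aged replicate 3 (highest 0.346), and perivascular genes without 6 of the 9 animals (highest 0.166, without middle-aged replicate 1) and in 13 of 23 settings in all. The MHC class I median was 0.02, 0.03 and 0.13 without middle-aged replicate 3, aged replicate 1 and aged replicate 3, and the pan-neuronal median −0.05 and −0.14 without middle-aged replicate 3 and aged replicate 3. Those of interferon-stimulated genes were 0.07 and 0.07 without the same pair. Without middle-aged replicate 1 complement was 0.10 and perivascular genes 0.13 (0.425 without aged replicate 2), and RVLM receptors were −0.14 and −0.05 without aged replicates 1 and 2. Without middle-aged replicate 3 the number of lists past the threshold was 11, against 18 with all animals.

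The transcription factor Zbtb16 differed between aged and middle-aged animals by −1.71 ± 0.22 (adjusted p = 0.08) and Igf2bp2 by −0.63 ± 0.10 (adjusted p = 0.15). Serpinb6b differed by −0.60 ± 0.09 (adjusted p = 0.14) and Hormad1 was at least 1.49-fold higher in the aged (adjusted p = 0.08). None of these 4 passed.

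**Figure D3:**
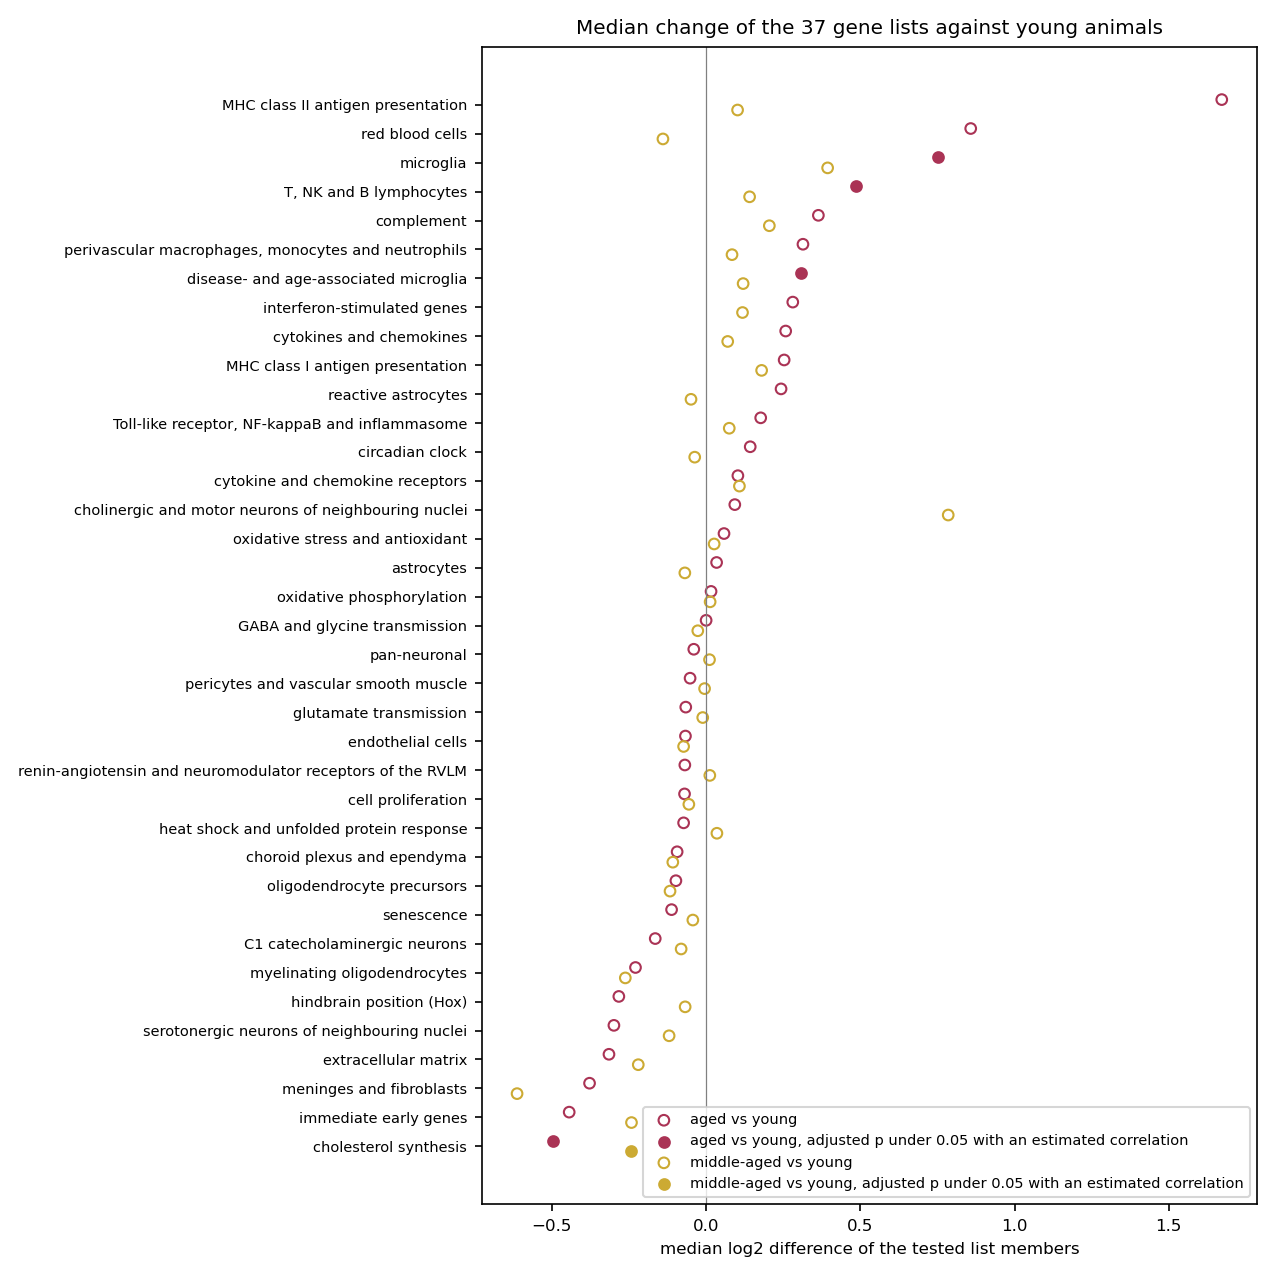
Median log2 difference from young animals of the 37 gene lists in middle-aged and aged animals; filled points have an adjusted p under 0.05 with an estimated correlation. Filled are cholesterol synthesis at both ages (−0.25 and −0.50) and microglia (0.75), lymphocytes (0.49) and disease- and age-associated microglia (0.31) in aged animals.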

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

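Fits with only technical replicate 2, on slide 1 alone and on slide 2 alone, and the form of the slide block, were chosen after seeing the data. The cause of a moved count was not tested, except that an adjusted p under 0.1 passes more items by construction and that leave-one-out fits and fits of only the groups compared hold fewer animals. Signal over background limits the dim genes: with 73.5% to 77.1% of spots well above background, folds of genes dark in 1 group are bounds, set by the floor of the main fit only.

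For aged against young animals 507 items passed, against 302 with normexp, 276 without the filter on dim probes, 304 with slide as a block, 774 with unadjusted p under 0.05 and at least 1.5-fold, and 877 with adjusted p under 0.1. Leave-one-out counts ran from 246 (without young replicate 3) to 477 (without middle-aged replicate 2). The share of calls that were higher was 74.2%, and ran from 66.8% (series matrix) to 83.9% (without young replicate 1), with 80.9% with slide as a block. For middle-aged against young animals 47 passed, against 19 with normexp, and 5 without the filter. It was 29 with only technical replicate 1, 31 with only technical replicate 2, 77 with 12 arrays and the animal as a random block, 28 with slide as a block, and 8 with the replicate block. It was 3 with only the groups compared, 0 on slide 1 alone (1602 with unadjusted p under 0.05), 304 with unadjusted p and fold, and 74 with adjusted p under 0.1. Leave-one-out counts ran from 2 (without middle-aged replicate 1 or 2) to 23 (without young replicate 1).

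For aged against middle-aged animals 1 item passed, against 4 with normexp, of which 2 were lower, 0 without the filter, 3 with probes well above background on all 12 arrays and 2 with only technical replicate 1. The count was 28 with 12 arrays and the animal as a random block, 0 with the replicate block, 11 with trend and robust moderation, and 3 with array weights. It was 0 with the series matrix, 0 on slide 2 alone (1783 with unadjusted p under 0.05), 411 with unadjusted p and fold, and 19 with adjusted p under 0.1. Leave-one-out counts ran from 0 (without young replicate 3, for example) to 3 (without young replicate 2). For any age 284 passed, against 142 without the filter, 174 with slide as a block, 148 with the replicate block, 765 with unadjusted p and fold, and 502 with adjusted p under 0.1. Leave-one-out counts ran from 71 (without young replicate 3) to 247 (without middle-aged replicate 2).

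Gene lists past the threshold numbered 24, 16 and 18 for aged against young, middle-aged against young and aged against middle-aged animals. They were 4, 1 and 2 by camera with an estimated correlation, 15, 5 and 10 by fry, and in leave-one-out fits 20 to 25, 15 to 21, and 11 (without middle-aged replicate 3) to 21 (without aged replicate 3). The replicate block gave 22, 17 and 15 lists and 343 items for aged against young animals, but numbers do not pair the samples: deviations of animals with the same number correlated at −0.411 to 0.37, and not every animal correlated best with its own number. Fits on slide 1 alone assume that the lone middle-aged animal varies like the others.

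Of 73 named genes called between aged and young animals, 30 passed in every setting other than a changed threshold or a fit of 1 slide, 38 in every leave-one-out fit, and 0 changed sign; 24 of the named genes not called were called in at least 1 setting. For middle-aged against young these were 2 of 16 by settings and by leave-one-out, with 0 sign changes and 5 newly called, and for aged against middle-aged 0 of 1, with 0 sign changes and 8 newly called. Among lists called, 14 of 24, 10 of 16 and 8 of 18 passed in every setting other than estimated-correlation camera, fry and fits of 1 slide. Their direction by camera did not change, but, fits of 1 slide aside, medians of 2, 2 and 0 changed sign in at least 1 setting: in aged against young animals meninges (0.01 without young replicate 1) and pan-neuronal genes (0.003 with the series matrix), and in middle-aged against young MHC class II (−0.005 with normexp) and lymphocyte genes (−0.07 with normexp, −0.02 without the filter). On slide 2 alone the circadian median in aged against middle-aged animals also did (−0.025). Over the 3 comparisons, calls of named genes ended for 38 without the filter, 33 with only the groups compared, 28 with the replicate block, 26 with slide as a block and 25 with normexp. They ended for 13 and 7 with only technical replicate 2 and 1, 11 with the series matrix, 7 with 12 arrays and the animal as a random block, 7 with the mean of a gene's probes and 6 with quantile normalization. Of the named genes not called, 3, 8 and 1 changed sign in at least 1 setting.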

Other observations

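The tests of slide, of the share of neurons, of blood and of the share of oligodendrocytes were chosen only after the results were seen; the counts of other splits of the animals were planned, and their recounts with other filters were added after.

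The clock genes Per2, Dbp and Bhlhe41, chosen after their values were seen, rose in aged against young animals by 0.75 ± 0.09 (adjusted p = 0.0043), 0.53 ± 0.07 (adjusted p = 0.0075) and 0.63 ± 0.09 (adjusted p = 0.0087). They differed by 0.83, 0.49 and 0.61 with slide as a block, where all 3 passed. The circadian list had 3 of 21 risen, 0 fallen, and 5 risen and 2 fallen adjusted over the list alone, with a median of 0.14 (camera adjusted p = 0.066; adjusted p = 0.203 with an estimated correlation; median 0.24 and adjusted p = 0.0255 with the block). In middle-aged against young animals its median was −0.04 and it did not pass (adjusted p = 0.971). Between aged and middle-aged animals it was higher by 0.18, with 6 risen adjusted over the list alone (camera adjusted p = 0.026; adjusted p = 0.186 with an estimated correlation), but not without middle-aged replicate 3 or aged replicate 3 (highest adjusted p = 0.107). Its median was 0.01 without aged replicate 3, 0.10 without middle-aged replicate 1 and −0.025 on slide 2, the opposite sign. The time of day of killing was not used here. Immediate early genes, which neurons and other cells switch on within minutes, were lower by −0.44 in aged and −0.24 in middle-aged against young animals (camera adjusted p = 0.000958 and 0.00136; adjusted p = 0.411 and 0.56 with an estimated correlation; −0.48 and −0.27 with the block). Without young replicate 1 these were −0.14 (adjusted p = 0.175) and −0.06 (adjusted p = 0.949), and without young replicate 2 they were −0.69 and −0.52. Of 26 members 1 passed in aged animals: Gadd45b, chosen after its values were seen, rose by 0.61 ± 0.10 (adjusted p = 0.017; lost without any 1 of the young animals, highest adjusted p = 0.0746). Heat shock genes, with 0 of 29 past over all items, were lower by −0.07 in aged against young (camera adjusted p = 0.0496; adjusted p = 0.339 with an estimated correlation; lost in 11 of 23 settings, normexp and the series matrix among them, 5 by leaving out an animal, highest adjusted p = 0.228; −0.03 and −0.05 without aged replicates 1 and 3). They were lower by −0.08 against middle-aged animals (camera adjusted p = 0.00122). This became adjusted p = 0.186 with an estimated correlation. Of 35 oxidative stress genes 3 rose in aged against young animals, all chosen after their values were seen: the NADPH oxidase subunits Ncf1 (1.13 ± 0.18, adjusted p = 0.02) and Cyba (0.74 ± 0.11, adjusted p = 0.015) and the heme oxygenase Hmox1 (0.39 ± 0.08, adjusted p = 0.049). With the block Cyba was 0.69 and passed, while Ncf1 was 1.12 ± 0.23 (adjusted p = 0.056) and Hmox1 0.37 ± 0.09 (adjusted p = 0.1), with larger SE. Calls were lost without young replicate 3 or aged replicate 1 for Cyba (highest adjusted p = 0.0665), without 5 of the 9 animals for Ncf1 (0.0725) and without 8 for Hmox1 (0.152). The list itself (median 0.06, adjusted p = 0.173) and oxidative phosphorylation (0.02, 0 of 53 past, adjusted p = 0.533, direction down) did not pass.

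Markers of neighbouring nuclei varied between animals. Young replicate 2, middle-aged replicate 3 and aged replicate 3, which lay apart on the second principal component, had the highest Hox medians of their groups (0.22, 0.28 and 0.17 against −0.63 to −0.01 in the other animals). They also had the lowest cholinergic and highest pan-neuronal medians of their groups. Genes of cholinergic and motor neurons were higher by 0.79 in middle-aged against young animals (camera adjusted p = 0.000481; adjusted p = 0.335 with an estimated correlation; 0.69 with slide as a block, 0.80 on slide 1 and −0.51 on slide 3). They were lower by −0.64 in aged against middle-aged animals (camera adjusted p = 0.000409; adjusted p = 0.327 with an estimated correlation; −0.64 with the block, −0.24 on slide 2 and −0.68 on slide 3). Of 12 members 0 passed in either count. Without young replicate 2 or middle-aged replicate 2 the first difference was 0.36 or 0.46, and without middle-aged replicate 2 or aged replicate 3 the other was −0.32 or −0.34. Relative to the young mean their medians in replicates 1 to 3 were 0.24, −0.74 and 0.60 in young, 0.80, 1.27 and 0.15 in middle-aged, and −0.25, 0.94 and −0.53 in aged animals. In aged against young animals the list had a median of 0.09 and a mean of −0.01 and did not pass (adjusted p = 0.552). Hox genes, which mark position along the hindbrain, were lower by −0.28 in aged against young animals (0 of 16 past over all items, 2 fallen adjusted over the list alone, camera adjusted p = 0.0104; adjusted p = 0.426 with an estimated correlation). With the block this was −0.13 (adjusted p = 0.102) and on slide 3 it was 0.47, the opposite sign, and the call was lost without young replicate 2 or aged replicate 2 (−0.10 and −0.17, adjusted p = 0.085 and 0.11). Without aged replicate 3 it was −0.45. Against middle-aged animals the aged were lower by −0.24 (camera adjusted p = 0.0189). The same list had adjusted p = 0.593 with an estimated correlation. It was lost without middle-aged replicate 3 or aged replicate 1 or 2 (highest adjusted p = 0.388). Without middle-aged replicate 3, aged replicate 2 and aged replicate 3 it was −0.10, −0.15 and −0.38. Normexp ended the call (5 of 23 settings in all). In aged against young animals, serotonergic (median −0.30, adjusted p = 0.114), endothelial (−0.07, adjusted p = 0.233), choroid plexus and ependymal (−0.09, adjusted p = 0.19) and pericyte and smooth muscle lists (−0.05, adjusted p = 0.35) did not pass. Nor did the proliferation (−0.07, adjusted p = 0.351) and senescence lists (−0.11, adjusted p = 0.0754). With the block the endothelial and senescence lists did (adjusted p = 0.0499 and 0.0488). Their fallen members were Mmp14 of the senescence list and, chosen after their values were seen, the vitronectin gene Vtn of the pericyte list (−0.46 ± 0.09, adjusted p = 0.046) and the cyclin gene Ccne2 of the proliferation list (−0.56 ± 0.07, adjusted p = 0.0048). With the block Ccne2 was −0.65 and passed, while Vtn was −0.50 ± 0.11 (adjusted p = 0.065), from a larger SE. Vtn also lost its call without any 1 of the 9 animals (highest adjusted p = 0.16).

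For any age the real split gave 284 items, the most of 100 drawn splits of the 9 animals (1 of 100 as large, highest other 22). There the filter on dim probes was held as the real groups define it. With the filter redefined by each split's own groups the counts were 284 and at most 35, and with probes well above background on all 12 arrays 276 and at most 35 (1 of 100 as large in each). A random grouping is thus an unlikely source of this count. Each pair of groups has 10 splits, too few for a share under 0.05. Real and highest other counts of items were 507 and 0 for aged against young, 47 and 0 for middle-aged against young (1 of 10 splits as large in each), and 1 and 1 for aged against middle-aged (2 of 10). Counts of lists by camera with the preset correlation were 24 and 23 (1 of 10), 16 and 19 (2 of 10) and 18 and 14 (1 of 10). The count of 19 came from the split with young replicate 1 beside middle-aged replicates 1 and 2.

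The first pattern is the set of 507 items that differ between aged and young animals, whose arrays lay mostly on different slides. If slide were the cause of the set as a whole, the differences would shrink with slide as a block, but the median ratio of blocked to unblocked difference was 0.977 (quartiles 0.905 and 1.061), and 505 of the 507 kept their sign. The block rests mainly on young replicate 3 and middle-aged replicate 3, the only animals on more than 1 slide, and with it 463 items passed between slides 3 and 1 and 20 between slides 2 and 1. With the block 304 items passed, so slide stays open as a source for single items. Age itself remains an open explanation, untested beyond the design.

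The second pattern is the rise of microglial genes. A lower share of neurons in the aged punches would raise markers of all other cells alike, but 102 markers of other non-neuronal cells had a median of −0.054 (quartiles −0.27 and 0.064) against 0.753 for microglial genes. Blood left in the tissue would tie microglial to red blood cell genes, yet the lowest microglial median of a middle-aged animal was 0.352 while the highest red blood cell median there was −0.088. How far blood adds to the further rise in aged animals, and to their higher lymphocyte, S100a9 and red blood cell values, stays open. More microglia, or more RNA of these genes per microglial cell, may be a source, a hypothesis from these data that was not tested here, and age itself stays open as untested.

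The third pattern is the fall of cholesterol synthesis genes. Fewer oligodendrocytes in the punches would lower myelin genes by at least as much. Yet in each aged animal cholesterol synthesis had the lower median (smallest gap −0.265, 0 shared genes). Young gaps (up to 0.032 in size) are near 0 by construction, as young means were subtracted. Myelin genes were mixed (adjusted over the list alone 10 fell and 4 rose), blunting the test. Middle-aged medians were alike (−0.25, myelin −0.26) with gaps of −0.173, −0.067 and −0.043. Fewer oligodendrocytes stay open there, and in part in the aged. For aged animals less RNA of these genes per cell, not measured, is an untested hypothesis. Age itself stays open, untested.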
